A study of Mus musculus with 36 samples.

How the data were processed

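The deposited files hold 1 library each, 36 in all, from endothelial cells, myocytes and fibroblasts of C57BL/6J mouse hearts, sham or 12 Gy, at 6 hours, 7 days and 28 days, with 2 libraries per group. Per the labels, RNA was extracted with RNeasy kits and libraries were made with a SMARTer mRNA-seq kit. The authors mapped to the mouse build that the labels name as GRCm38 or mm10. The aligner and the counting tool are not given in the sources used here. The first value column of each deposited file holds read counts, whole numbers per RefSeq transcript (33068 transcripts, 24061 gene names), with every isoform counted on its own. The second column is called TPM per the file headers, but its values equal RPKM (reads per kilobase of transcript, scaled to all reads), with a largest difference of 1.8e-12, so it is called RPKM here. A further 30 read columns of other libraries that sit in some of the deposited files were not used.

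For each of 4914 gene names with more than 1 transcript, the transcript with the most reads over all libraries stood for the gene. Coordinates came from the GRCm38.p6 RefSeq annotation, which held 23760 of the gene names. Among genes with over 100 reads, 42 had counts equal to another gene in all libraries, as hemoglobin paralogs do. The libraries held 25.91 to 45.49 M reads in endothelial, 10.18 to 19.42 M in myocyte and 25.63 to 31.94 M in fibroblast cells. The common biological coefficient of variation was 0.096 in endothelial, 0.172 in myocyte and 0.068 in fibroblast libraries.

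Groups, comparisons, tests, gene lists and the rule for naming genes were chosen before the data were examined. For each cell type, the 12 libraries were fitted with edgeR 4.0.16 (R 4.3.3) as a group means model with TMM library sizes, filterByExpr (minimum count 10, minimum total 15), glmQLFit and glmQLFTest. Irradiated minus sham was tested at each time, in 9 comparisons, and an F-test asked whether that difference changed between times (3 tests, 1 per cell type). A fit of all 36 libraries asked with the same test whether it differed between cell types at each time (3 tests). Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Fold changes are 2 to the power of the fitted log2 fold change, and SE is that of the fitted contrast.

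The 35 gene lists comprise 22 program lists and 13 cell type marker lists (629 genes, 626 of them in the files, 4 under an older symbol). Each list was tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over all lists and the 9 comparisons. Camera with an estimated correlation between genes, and fry, were run beside it. Members past 0.05 were counted with p-values adjusted over all genes and adjusted over the list alone. Differences of lists between times or cell types were given for p-values with an estimated correlation. Marker levels in sham libraries are the mean log2(CPM + 1) of a list per library, with a pseudocount of 1. They were compared between cell types with an exact two-sided permutation test of 6 against 6 libraries in Python 3.11.15, adjusted over 39 list and cell type pairs.

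Genes were named by rule. Per comparison these were, first, genes past 0.05 with a mean of at least 5 CPM, a symbol that is not a predicted or clone name and both irradiated libraries on the same side of both sham libraries: the 6 with the largest and the 6 with the smallest log2 fold change. Second came the 2 members with the smallest p of each list with members past 0.05, and last 12 genes in every comparison whatever their p (Cdkn1a, Mdm2, Ccng1, Mki67, Top2a, Isg15, Ccl2, Col1a1, Postn, Gja1, Nppa and another that is not reported here). For the difference tests the 6 genes with the smallest p were eligible, and for marker levels a fixed set of genes. The text names a part of those that the rule allows, and besides them Fras1, Zfp365 and Cyp1a1 among the few genes called in myocyte libraries at 7 and 28 days, chosen after their values were seen.

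The alternatives were RLE size factors, no low-count filter beyond 1 read, a filter at a mean of 5 CPM, library sizes without hemoglobin and ribosomal RNA genes, DESeq2 1.42.0, limma on log2(RPKM + 1), a single fit of all 36 libraries, a fit of the comparison's 4 libraries, the replicate number as a block (its counts, such as 432 genes for fibroblast libraries at 7 days, are in the closing section), and each library left out in turn. The design had planned limma on log2(TPM + 1); it was run on RPKM since that is what the column holds. For markers, the median replaced the mean and RPKM replaced CPM. Chosen after the data were seen were counts summed over all transcripts of a gene, a replicate block within each time, and a fit without the first irradiated myocyte library of 7 days.

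The fits were tested on simulated data with the measured dispersions and 200 changed genes per cell type at 7 days. The myocyte dispersions were measured with the first irradiated library of 7 days included. In the test of irradiated against sham, 85.7% of genes changed 2-fold were recovered in endothelial, 32% in myocyte and 74% in fibroblast libraries, and of those changed 4-fold 98%, 94% and 89.8%. False calls made up 1.2%, 9.7% and 5% of all calls, and no gene was called where nothing had been changed. No gene name in the files carried the mt- prefix of mitochondrial genes. Figures were drawn with matplotlib 3.10.9, and tables were handled with numpy 2.4.6 and pandas 2.3.3.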

Results

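RNA was sequenced from endothelial cells, myocytes and fibroblasts of hearts of C57BL/6J mice that had received either a sham procedure or a single fraction of 12 Gy from a small animal microirradiator. Cells were taken 6 hours, 7 days and 28 days after treatment. The 36 libraries form 18 groups of 2, and each cell type has 12 libraries. The series asks how radiation changes gene expression in each cardiac lineage and how that change differs between times. Counting the transcript with the most reads for each gene, endothelial libraries held 25.91 to 45.49 M reads, fibroblast libraries 25.63 to 31.94 M and myocyte libraries 10.18 to 19.42 M. Between 16922 and 17661 genes had at least 1 read in endothelial libraries, 16997 to 17574 in fibroblast libraries and 16085 to 17160 in myocyte libraries. Levels are counts scaled to library size (CPM), given as mean ± SD (n = 2 libraries per group), and log2 fold changes of irradiated over sham are given ± SE. The p-values measure only the spread between these libraries, since nothing in the labels says whether replicates came from separate animals. Coordinates are those of mouse build GRCm38.

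The sham libraries showed how far each preparation held its named cell type. Mean log2(CPM + 1) of the cardiomyocyte markers was 11.60 ± 0.12 in myocyte libraries (SD, n = 6), 4.94 ± 0.21 in endothelial libraries and 3.38 ± 0.25 in fibroblast libraries. Myh6 (chromosome 14, 54941921 to 54968017), the main myosin heavy chain of the adult mouse heart, stood at 42800 ± 4060 CPM in myocyte libraries and at 81.8 ± 18.3 CPM in endothelial libraries. Endothelial markers were highest in endothelial libraries at 10.32 ± 0.09, yet reached 7.73 ± 0.34 in myocyte libraries against 3.77 ± 0.34 in fibroblast libraries. The junction gene Cdh5 stood at 2510 ± 193 CPM in endothelial, 420 ± 126 CPM in myocyte and 3.91 ± 2.71 CPM in fibroblast libraries. Fibroblast markers had means of 10.91 in fibroblast, 7.28 in myocyte and 7.04 in endothelial libraries. The receptor gene Pdgfra stood at 1080 ± 44.4 CPM in fibroblast and 81.6 ± 21.9 CPM in myocyte libraries. Macrophage and monocyte markers had a mean of 4.57 ± 0.27 in myocyte libraries, above 1.53 in endothelial and 0.92 in fibroblast libraries, and the lysozyme gene Lyz2 stood at 288 ± 51.1 CPM in myocyte libraries. Mesothelial markers were highest in fibroblast libraries, at 7.30 ± 0.41. Of 39 comparisons of a marker list between a pair of cell types, 30 passed an exact two-sided permutation test of 6 against 6 libraries after adjustment, and the smallest p that this test can give is 0.00216. The heat map of marker levels shows every list in every library.

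**Figure D1:**
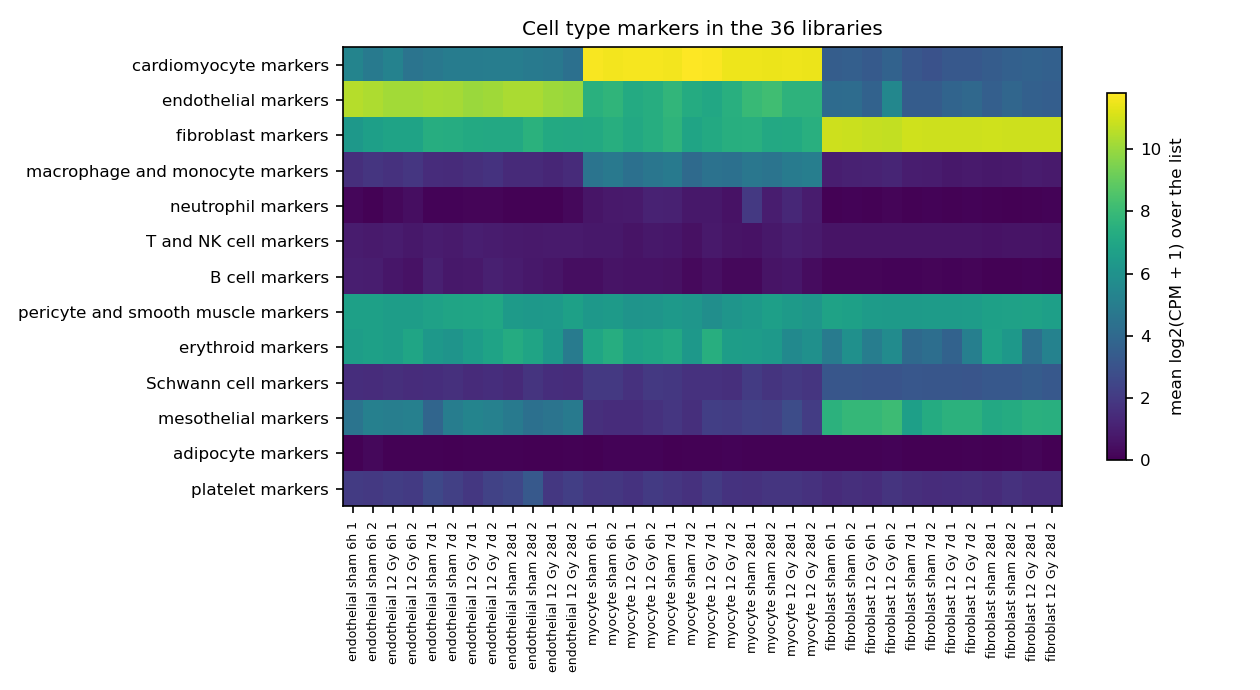
Mean log2(CPM + 1) of 13 marker lists (vertical axis) in each of the 36 libraries (horizontal axis, by cell type, time and treatment), drawn as a colour scale. Cardiomyocyte markers are brightest in the 12 myocyte libraries, endothelial markers in the endothelial and fibroblast markers in the fibroblast libraries, and endothelial and macrophage markers are also visible in the myocyte libraries.

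At 6 hours, endothelial libraries showed a broad rise of p53 targets, the genes that the DNA damage responsive factor p53 switches on. Of 32 measured targets, 28 were higher in irradiated than in sham libraries and none was lower (29 and 1 adjusted over the list alone), with a median log2 fold change of 1.87. Cdkn1a (chromosome 17, 29090979 to 29100722), which codes for the cell cycle inhibitor p21, rose from 349 ± 121 to 1280 ± 19.3 CPM (log2 fold change 1.88 ± 0.17, adjusted p = 1.39e-05). Mdm2 (chromosome 10, 117688875 to 117710758), whose product degrades p53, rose 4.82-fold, and Ccng1 (chromosome 11, 40748552 to 40755309), which codes for cyclin G1, rose 6.7-fold. Among the largest rises were those of Celf5 (72.2-fold, from 0.335 ± 0.154 CPM), Gtse1 (42.6-fold), Zfp365 (37.1-fold) and Gdf15 (29.3-fold), which codes for a stress-induced secreted factor. Sesn2, a stress-responsive gene of the p53 list, rose 21.5-fold. This list passed the camera test also with an estimated correlation between genes (adjusted p = 0.00106).

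Other gene groups moved in the same endothelial libraries at 6 hours. Of 42 cell cycle genes, 23 were lower and none was higher (30 lower adjusted over the list alone), among them Ccnb1, the mitotic cyclin B1 (log2 fold change -2.77 ± 0.28), and Prc1, a regulator of cytokinesis (-1.46 ± 0.14). The list had a median of -0.60 and passed with the preset correlation, with adjusted p = 0.247 with an estimated correlation. Of 29 genes for inflammatory cytokines and adhesion, 10 were higher and none was lower (10 adjusted over the list alone), with Lif, a cytokine of the interleukin-6 family, up 19.8-fold and the adhesion molecule gene Selp up 2.87-fold (list adjusted p = 0.461 with an estimated correlation). Of 16 antioxidant response genes, 6 were higher (8 higher and 1 lower adjusted over the list alone), led by the metallothionein genes Mt2 (6.65-fold) and Mt1 (2.77-fold), and the list had adjusted p = 0.259 with an estimated correlation. Glucocorticoid-responsive genes were called higher as a list although their median was -0.04, since their mean was 0.39: 3 of 11 were higher and 1 was lower (5 and 2 adjusted over the list alone; list adjusted p = 0.326 with an estimated correlation). Of 17 Notch pathway genes, 7 were lower (1 higher and 8 lower adjusted over the list alone), including Lfng (-0.88 ± 0.15); the list had adjusted p = 0.516 with an estimated correlation and 0.275 without the first irradiated library. Of 22 immediate-early genes, 4 were higher (7 adjusted over the list alone); the list had adjusted p = 0.854 with an estimated correlation, 0.124 without the second sham library and 0.82 without the first irradiated library. Cyp1a1, a target of the aryl hydrocarbon receptor, fell by 2.41 ± 0.36 on the log2 scale, and the apelin receptor gene Aplnr fell to 0.476 of its sham level.

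Markers of cell types also moved in the endothelial libraries at 6 hours. Endothelial markers fell as a list, with 5 of 20 genes lower (10 adjusted over the list alone), including the junction gene Cldn5 (-0.69 ± 0.13), and adjusted p = 0.524 with an estimated correlation. Fibroblast markers were called higher, with 4 of 18 genes higher (5 adjusted over the list alone), among them the matrix metalloproteinase gene Mmp2 (3.18-fold). That call had adjusted p = 0.811 with an estimated correlation and 0.168 without the first sham library. The edgeR quasi-likelihood test, adjusted over all genes by the Benjamini-Hochberg method, called 1690 of 14919 genes at 6 hours, 910 higher and 780 lower. The count was 826 without the first sham library and 983 without the second irradiated library, and limma on log2(RPKM + 1) split its calls into 1013 higher and 504 lower.

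At 7 days, endothelial p53 targets were still higher, with 24 of 32 genes higher and none lower (27 adjusted over the list alone), a median log2 fold change of 1.15 and adjusted p = 0.000815 with an estimated correlation. Gdf15 (chromosome 8, 70629393 to 70632470) rose from 10.8 ± 0.0117 to 142 ± 5.01 CPM (13.2-fold, adjusted p = 5.93e-08). Zfp365 rose 13.0-fold, Sesn2 8.83-fold, Phlda3, a p53-induced repressor of Akt signalling, 4.13-fold and Cdkn1a 2.77-fold. Cell cycle genes were lower: 25 of 42 fell and none rose (31 adjusted over the list alone), with a median of -1.05 and adjusted p = 0.00834 with an estimated correlation. Mki67 (chromosome 7, 135689784 to 135716450), the proliferation marker, fell from 23.2 ± 6.23 to 3.9 ± 0.763 CPM (log2 fold change -2.59 ± 0.21, adjusted p = 1.4e-05). Top2a (chromosome 11, 98992947 to 99024199), the topoisomerase of dividing cells, fell by 2.11 ± 0.19 on the log2 scale.

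Circadian clock genes rose as a list at 7 days in endothelial libraries, with 10 of 16 higher and 1 lower (12 and 3 adjusted over the list alone), a median of 0.66 and adjusted p = 0.0395 with an estimated correlation. The clock output genes Dbp and Tef rose 2.74-fold and 1.88-fold. The sample titles give no hour of day at which cells were taken. Whether that hour differed between sham and irradiated libraries could not be tested, here or for clock genes in the other comparisons. Ltc4s, which codes for leukotriene C4 synthase, rose 7.57-fold. Other list calls at 7 days held with the preset correlation alone. Interferon-stimulated genes were lower (4 of 41, or 21 adjusted over the list alone; adjusted p = 0.461 with an estimated correlation). MHC class I presentation had a median of -0.29, with 0 of 16 genes called over all genes and 10 lower adjusted over the list alone (adjusted p = 0.461 with an estimated correlation), and MHC class II presentation had a median of -0.47 (0 of 8, 4 lower adjusted over the list alone, adjusted p = 0.516 with an estimated correlation). Immediate-early genes had a median of 0.21 (0 of 22 called, adjusted p = 0.723 with an estimated correlation). Markers moved as well: endothelial markers had a median of -0.15 (adjusted p = 0.598 with an estimated correlation). Fibroblast markers had a median of -0.16, with adjusted p = 0.856 with an estimated correlation, 0.0728 without the first sham library and 0.202 without the second irradiated library. Mesothelial markers had a median of 0.85, with adjusted p = 0.568 with an estimated correlation and 0.229 without the first sham library. At 7 days 271 of 14919 genes were called by edgeR, 138 higher and 133 lower, and the count was 157 without the first sham library and 155 without the second irradiated library.

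At 28 days the endothelial cell cycle genes were higher than in sham libraries. Of 42 genes, 35 were higher and none was lower (38 adjusted over the list alone), with a median log2 fold change of 1.61 and adjusted p = 0.00834 with an estimated correlation. Mki67 rose from 15.7 ± 1.61 to 59.2 ± 5.61 CPM (log2 fold change 1.91 ± 0.19, adjusted p = 5.43e-05), and Top2a rose 4.08-fold, Prc1 3.88-fold and the spindle gene Tpx2 3.52-fold. p53 targets remained called, with 21 of 32 higher and 2 lower (22 and 3 adjusted over the list alone), a median of 1.01 and adjusted p = 0.00951 with an estimated correlation. Gdf15 rose 12.4-fold, Phlda3 3.96-fold, Cdkn1a 2.51-fold, Ccng1 2.21-fold and Mdm2 1.69-fold. Apln (chromosome X, 48025146 to 48034853), which codes for the vascular peptide apelin, rose from 48.0 ± 5.91 to 455 ± 58.0 CPM (log2 fold change 3.24 ± 0.21, adjusted p = 1.88e-06). The endothelial gene Prnd rose 7.14-fold, Ltc4s 8.14-fold and the placental growth factor gene Pgf 2.04-fold.

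In endothelial libraries at 28 days, of 41 interferon-stimulated genes, 20 were higher and none was lower (23 and 2 adjusted over the list alone), with the chemokine gene Cxcl10 up 5.3-fold, Ifi27l2a up 2.19-fold and Isg15 up 2.02-fold (list adjusted p = 0.396 with an estimated correlation). Of 29 inflammatory genes, 8 were higher and none was lower (13 adjusted over the list alone), including the monocyte chemokine gene Ccl2 (3.32-fold) and Lif (3.09-fold; list adjusted p = 0.656 with an estimated correlation). Basement membrane genes were called higher, 4 of 13 over all genes (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.734 with an estimated correlation), with Nid2 up 1.83-fold. The matrix glycoprotein gene Tnc rose 2.63-fold. Lower were Cyp1a1 (log2 fold change -4.13 ± 0.42), Car4, a capillary carbonic anhydrase gene (-1.89 ± 0.16), the lipoprotein lipase gene Lpl (-1.06 ± 0.18) and the clock gene Per3 (-1.01 ± 0.15). Of 16 circadian genes, 7 were lower (8 adjusted over the list alone; list adjusted p = 0.414 with an estimated correlation). Cholesterol synthesis genes had a median of 0.21 with 1 of 19 higher (adjusted p = 0.811 with an estimated correlation, 0.0572 without the second sham library and 0.336 without the second irradiated library). Antioxidant genes had a median of 0.16 with 3 of 16 higher (6 adjusted over the list alone; adjusted p = 0.516 with an estimated correlation, 0.05 without the second sham library and 0.0929 without the second irradiated library).

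Markers of endothelial cells and of other cells were lower as lists in the same irradiated libraries at 28 days. All 6 erythroid markers were lower, with a median of -1.42 and adjusted p = 0.461 with an estimated correlation, and hemoglobin genes took 0.302% and 0.227% of reads in the sham libraries and 0.147% and 0.059% in the irradiated ones. Of 6 platelet markers, 4 were lower (5 adjusted over the list alone), with adjusted p = 0.683 with an estimated correlation, 0.0557 without the second sham library and 0.0867 without the first irradiated library. Endothelial markers had 5 of 20 genes lower (9 adjusted over the list alone), including the water channel gene Aqp1 (-0.79 ± 0.15), and adjusted p = 0.569 with an estimated correlation. Cardiomyocyte markers had a median of -0.41 with 1 of 20 lower (adjusted p = 0.856 with an estimated correlation, 0.12 without the first sham library and 0.223 without the second irradiated library). The edgeR test called 1487 of 14919 genes, 853 higher and 634 lower. The count was 647 without the first sham library, 443 without the second, 2317 without the first irradiated library and 654 without the second.

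The radiation effect differed between the 3 times for 934 of 14919 genes in endothelial libraries (edgeR F-test). Cell cycle genes had some of the smallest p-values: Prc1 had log2 fold changes of -1.46 at 6 hours, -1.81 at 7 days and 1.96 at 28 days (adjusted p = 1.15e-06), and Anln, a gene of the dividing cell's contractile ring, had -0.85, -1.70 and 2.00 (adjusted p = 4.23e-06). The cell cycle list differed between 28 and 7 days (median difference 2.51, adjusted p = 0.00192 with an estimated correlation) and between 28 days and 6 hours (2.20, adjusted p = 0.00826 with an estimated correlation). The rise of Ccng1 was 2.74 at 6 hours, 1.86 at 7 days and 1.15 at 28 days (adjusted p = 3.22e-05 for a difference), and that of Mdm2 was 2.27, 1.35 and 0.76 (adjusted p = 0.000175). For Cdkn1a a difference between times was not detected (adjusted p = 0.317; 0.00596 without the first 6-hour sham library). The count of 934 was 580 without the first sham library at 6 hours, 505 without the first and 441 without the second sham library at 28 days, and 1504 without the first irradiated library at 28 days. The plot of levels in each library shows 3 p53 targets and 2 cell cycle genes in all groups.

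**Figure D2:**
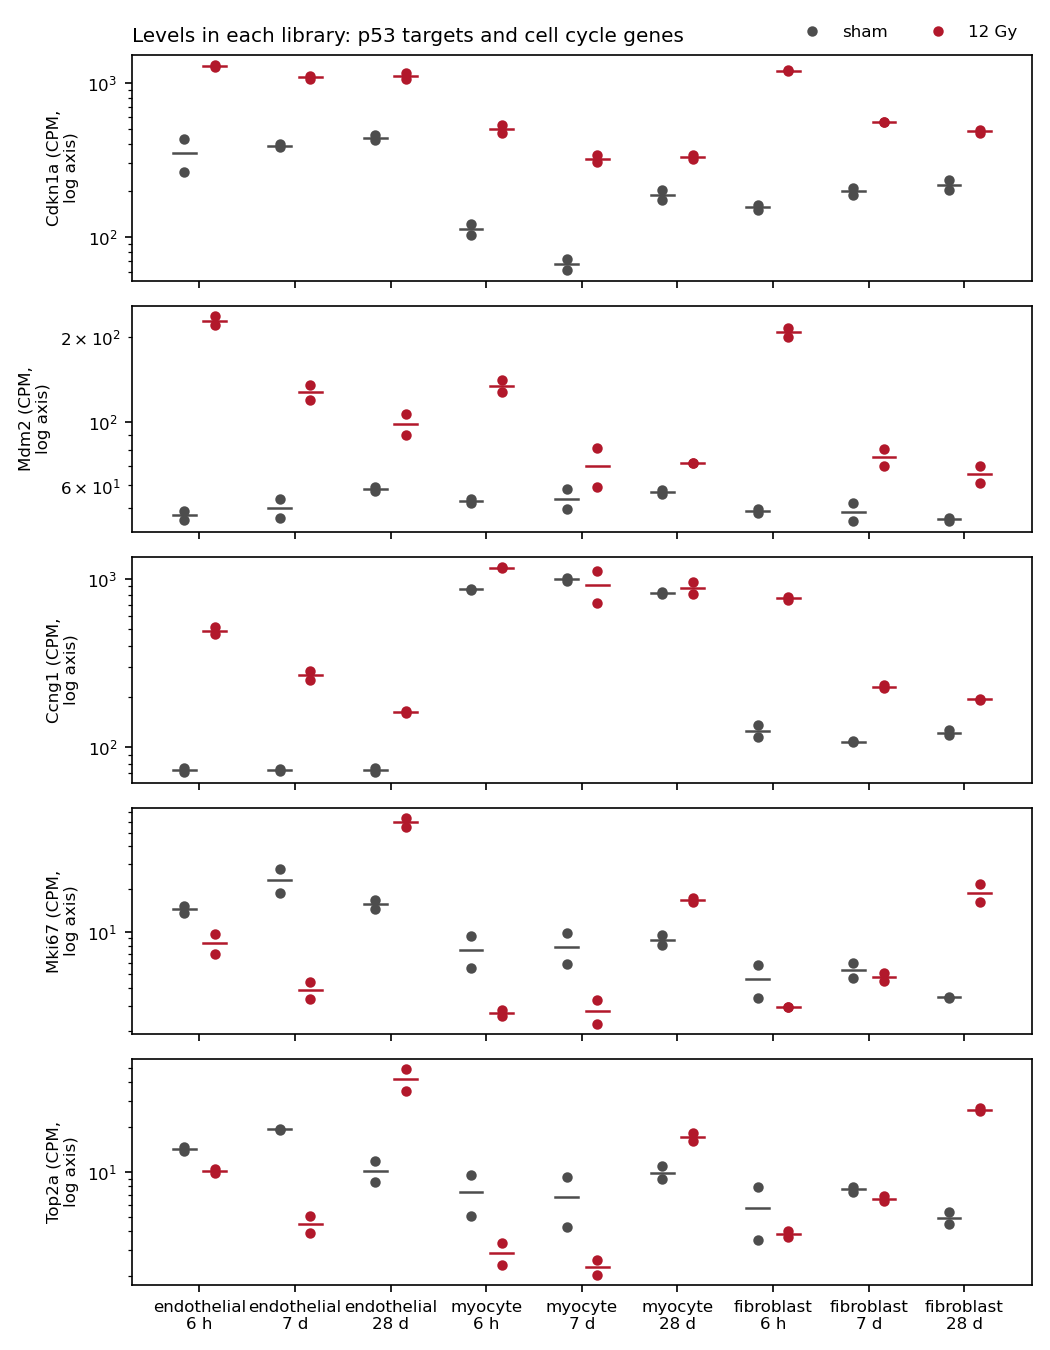
CPM (vertical log axes) of Cdkn1a, Mdm2, Ccng1, Mki67 and Top2a in each of the 36 libraries, by cell type and time, with sham libraries in grey and 12 Gy libraries in red, and a line at each group's mean (n = 2). In endothelial libraries Mki67 lies below sham at 7 days (3.9 against 23.2 CPM) and above it at 28 days (59.2 against 15.7 CPM), while Cdkn1a lies above sham at every time.

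Fibroblast libraries at 6 hours had 1843 genes higher and 1850 lower of 14998 tested (edgeR). Of the 32 p53 targets, 28 were higher and 1 was lower (29 and 1 adjusted over the list alone), with a median log2 fold change of 1.84 and adjusted p = 4.58e-05 with an estimated correlation. Cdkn1a rose from 156 ± 6.98 to 1190 ± 5.91 CPM (log2 fold change 2.93 ± 0.08, adjusted p = 1.94e-11), Sesn2 rose 9.91-fold, the p53-induced nuclease gene Aen 6.26-fold, Ccng1 6.11-fold and Mdm2 4.23-fold. The acute phase gene Saa3 rose 23.6-fold.

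Inflammatory, interferon and antigen presentation genes were higher in fibroblast libraries at 6 hours. Of 26 inflammatory genes, 14 were higher and none was lower (15 adjusted over the list alone), among them the adhesion molecule gene Icam1 (3.65-fold), Ccl2 (2.68-fold) and the transcription factor gene Nfkb2 (1.94-fold; list adjusted p = 0.414 with an estimated correlation). Of 41 interferon-stimulated genes, 26 were higher and 2 lower (28 and 3 adjusted over the list alone), including Gbp2 (3.35-fold) and Isg15 (2.14-fold; list adjusted p = 0.524 with an estimated correlation). MHC class I genes were higher in 15 of 16 cases, with the peptide transporter gene Tap1 up 3.01-fold and H2-Q4 up 1.64-fold (list adjusted p = 0.461 with an estimated correlation). Of 16 antioxidant genes, 7 were higher (10 higher and 1 lower adjusted over the list alone), including Sod2 (2.16-fold) and Txnrd1 (1.85-fold; list adjusted p = 0.282 with an estimated correlation). Lcn2, which codes for the iron-binding secreted protein lipocalin-2, rose 17.7-fold.

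Matrix, contractile and clock genes were lower in the same fibroblast libraries. Of 36 extracellular matrix genes, 15 were lower and 4 higher (19 and 4 adjusted over the list alone), with the growth factor gene Tgfb3 at -0.77 ± 0.07 and Mmp2 going the other way at 0.77 ± 0.06 (list adjusted p = 0.734 with an estimated correlation). Of 12 pericyte and smooth muscle markers, 6 were lower and 1 higher (7 and 1 adjusted over the list alone), including the smooth muscle actin gene Acta2 (-0.84 ± 0.09); the list had adjusted p = 0.496 with an estimated correlation and 0.0538 without the first sham library. Of 16 circadian genes, 9 were lower and 2 higher (10 and 3 adjusted over the list alone), including Hlf (-1.41 ± 0.08) and Bhlhe41 (-0.95 ± 0.08; list adjusted p = 0.208 with an estimated correlation). Inmt, a methyltransferase gene, fell by 1.62 ± 0.10 and the fibroblast receptor gene Pdgfra by 0.70 ± 0.06 on the log2 scale, while the gap junction gene Gja1 rose 1.91-fold. The second irradiated library stood apart in endothelial markers, at a mean log2(CPM + 1) of 5.44 against 3.71 in the first and 4.12 and 4.18 in the sham libraries, and Pecam1 stood at 52.6 CPM in it and 10.6 CPM in the first. Endothelial markers as a list were not called (adjusted p = 0.638), and were lower without that library (adjusted p = 0.0023). Without it the count of genes was 2198 in place of 3693, and the fit of all 36 libraries called 850 higher and 460 lower.

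At 7 days, fibroblast p53 targets remained higher, with 21 of 32 genes higher and none lower (24 adjusted over the list alone), a median of 0.71 and adjusted p = 4.58e-05 with an estimated correlation. Cdkn1a rose from 199 ± 13.1 to 553 ± 0.79 CPM (log2 fold change 1.48 ± 0.08, adjusted p = 8.56e-08), Psrc1 rose 5.19-fold, Eda2r, a death receptor family gene, 3.7-fold, Sesn2 3.16-fold and Ccng1 2.11-fold. The chloride channel family gene Ano3 rose 4.19-fold and Mmp2 1.47-fold. Pdgfra fell by 0.48 ± 0.06 and Lrrc55 by 0.89 ± 0.10 on the log2 scale. Mki67 had a log2 fold change of -0.16 ± 0.22, which did not pass (adjusted p = 0.855); it was 0.03 without the first sham library (adjusted p = 0.992).

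Smaller list calls in fibroblast libraries at 7 days held with the preset correlation alone. Of 41 interferon-stimulated genes, 10 were higher (16 higher and 1 lower adjusted over the list alone; list adjusted p = 0.516 with an estimated correlation), and MHC class I genes had 1 of 16 higher (6 adjusted over the list alone; adjusted p = 0.516 with an estimated correlation). Mesothelial markers had a median of 0.64, with 2 of 7 higher (7 adjusted over the list alone; adjusted p = 0.359 with an estimated correlation), and endothelial markers had a median of 0.61 with 1 of 20 lower, so that the list and its single called gene went opposite ways (adjusted p = 0.811 with an estimated correlation). The 4 further lists lost their call with an estimated correlation and without some libraries. Inflammatory genes had 1 of 26 higher (adjusted p = 0.742 with an estimated correlation, 0.199 without the second sham library and 0.318 without the second irradiated library). Extracellular matrix genes had 3 of 36 higher and 1 lower (adjusted p = 0.778, and 0.412 and 0.322 without the same libraries). Cell cycle genes had a median of -0.15 (adjusted p = 0.778 with an estimated correlation, 0.0754 without the first sham library and 0.117 without the second irradiated library). Circadian genes had 2 of 16 higher and 1 lower (adjusted p = 0.461 with an estimated correlation, 0.0734 and 0.0619 without the first and second sham library and 0.0775 without the first irradiated library). The edgeR test called 276 of 14998 genes, 227 higher and 49 lower. The count was 102 without the first sham library, 435 without the second, 133 without the first irradiated library and 101 without the second.

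At 28 days, interferon-stimulated genes were higher in fibroblast libraries, in 39 of 41 cases (40 adjusted over the list alone), with a median log2 fold change of 0.88 and adjusted p = 0.00834 with an estimated correlation. Irf7 (chromosome 7, 141263183 to 141266499), a transcription factor of the interferon response, rose from 20.3 ± 0.565 to 80.0 ± 1.45 CPM (log2 fold change 1.98 ± 0.10, adjusted p = 1.57e-07), Oas1a, which senses double-stranded RNA, rose 4.81-fold, Isg15 3.23-fold and Bst2 2.19-fold. Cell cycle genes were higher as well, in 25 of 42 cases with none lower (29 adjusted over the list alone), with a median of 1.26 and adjusted p = 0.00834 with an estimated correlation. Mki67 rose from 3.45 ± 0.0286 to 18.8 ± 3.86 CPM (log2 fold change 2.45 ± 0.21, adjusted p = 1.03e-05), Top2a rose 5.26-fold and Ccnb1 9.1-fold. Of 32 p53 targets, 20 were higher (23 higher and 1 lower adjusted over the list alone), with a median of 0.61 and adjusted p = 0.000117 with an estimated correlation: Cdkn1a rose 2.21-fold, Sesn2 2.79-fold and Ccng1 1.58-fold.

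Antigen presentation and matrix genes followed in fibroblast libraries at 28 days. MHC class I genes were higher in 11 of 16 cases (14 adjusted over the list alone), with Tap1 up 1.83-fold and H2-K1 up 1.74-fold (list adjusted p = 0.0776 with an estimated correlation). Of 26 inflammatory genes, 6 were higher and 1 lower (12 and 2 adjusted over the list alone; list adjusted p = 0.568 with an estimated correlation). Of 36 extracellular matrix genes, 7 were higher and 1 lower (18 and 2 adjusted over the list alone), with Mmp2 up 1.35-fold and the fibroblast activation protein gene Fap down at -0.67 ± 0.07 (list adjusted p = 0.598 with an estimated correlation). Postn, which codes for the matrix protein periostin, rose 1.52-fold (adjusted p = 0.00589; 0.104 without the second sham library). Cd83 fell by 0.92 ± 0.08, Pgf by 0.73 ± 0.09 and Pdgfra by 0.45 ± 0.06 on the log2 scale. Erythroid markers were lower as a list, with 3 of 6 lower (6 adjusted over the list alone), a median of -1.85 and adjusted p = 0.414 with an estimated correlation; hemoglobin genes took 0.246% and 0.161% of reads in the sham and 0.035% and 0.074% in the irradiated libraries. Hbb-bs and Hbb-b1 had equal counts in every library, so their reads cannot be told apart.

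Smaller list calls in fibroblast libraries at 28 days were lost under several settings. Circadian genes had 2 of 16 lower (3 adjusted over the list alone; adjusted p = 0.461 with an estimated correlation, 0.0854 without the first sham library and 0.153 without the first irradiated library). MHC class II genes had a median of 0.60 with 0 of 7 called (adjusted p = 0.598 with an estimated correlation, 0.0633 and 0.065 without the first and second sham library and 0.212 without the first irradiated library). Heat shock genes had a median of -0.12 (adjusted p = 0.516 with an estimated correlation, 0.195 without the first sham library and 0.214 without the second irradiated library). Mesothelial markers had a median of 0.28 (adjusted p = 0.811 with an estimated correlation, 0.114 without the first sham library, and 0.0688 and 0.0523 without the first and second irradiated library). In all, edgeR called 494 of 14998 genes, 372 higher and 122 lower, and the count was 244 without the first sham library and 229 without the second. limma on log2(RPKM + 1) split its calls into 354 higher and 56 lower, and the fit of all 36 libraries into 178 higher and 10 lower.

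The radiation effect differed between times for 1484 of 14998 genes in fibroblast libraries (edgeR F-test). Rdh10, a retinol dehydrogenase gene, had log2 fold changes of 1.98 at 6 hours, -0.01 at 7 days and -0.20 at 28 days (adjusted p = 1.69e-08), and Wisp2, a secreted modulator of Wnt signalling, had -1.12, 0.60 and 0.46 (adjusted p = 1.35e-07). Ccng1 had 2.61, 1.08 and 0.66 (adjusted p = 2.71e-07) and Cdkn1a had 2.93, 1.48 and 1.14 (adjusted p = 6.22e-07). The p53 list differed between 7 days and 6 hours (median difference -1.06) and between 28 days and 6 hours (-1.13), each with adjusted p = 0.000394 with an estimated correlation. Cell cycle and interferon-stimulated genes differed between 28 and 7 days (median differences 1.51 and 0.62), with adjusted p = 0.00817 and 0.0394 with an estimated correlation. Col1a1, the main collagen gene, had log2 fold changes of -0.25, 0.18 and 0.28 (adjusted p = 0.00655 for a difference), and Postn had -0.32, 0.38 and 0.60 (adjusted p = 0.00398). Without the second irradiated library at 6 hours the count was 901.

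**Figure D3:**
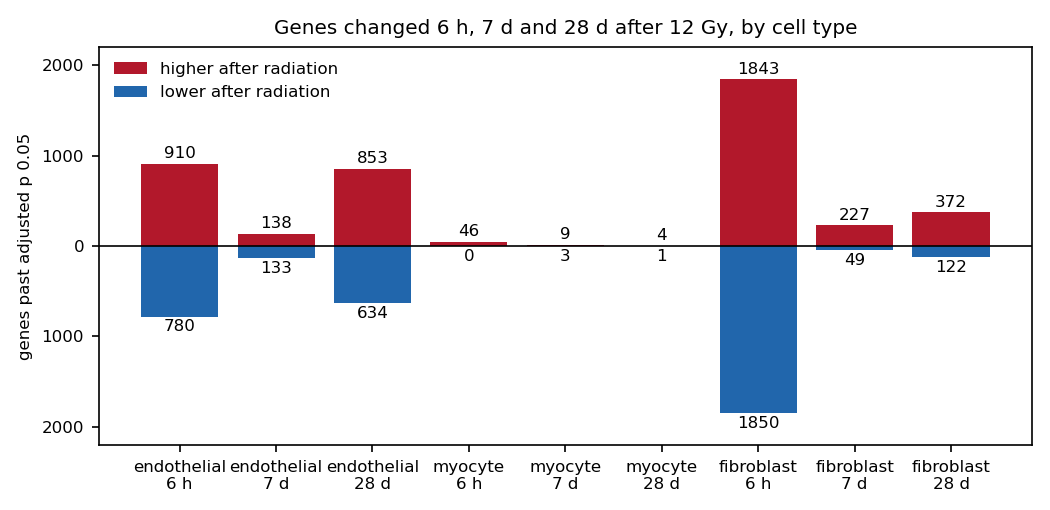
Number of genes past an adjusted p of 0.05 (vertical axis; higher after radiation above 0, lower below 0) in each cell type and time (horizontal axis; n = 2 sham and 2 irradiated libraries each). Fibroblast libraries at 6 hours have the longest bars (1843 higher, 1850 lower), and myocyte libraries have 46, 9 and 4 genes higher.

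In myocyte libraries, p53 targets were higher at 6 hours, with 17 of 32 genes higher and none lower (22 adjusted over the list alone), a median log2 fold change of 1.33 and adjusted p = 0.000117 with an estimated correlation. Cdkn1a rose from 113 ± 12.9 to 501 ± 42.2 CPM (log2 fold change 2.15 ± 0.17, adjusted p = 0.000432). Gtse1 (chromosome 15, 85859691 to 85876573), a p53-binding regulator of the cell cycle, rose 30.5-fold, Celf5 30.8-fold, Zfp365 11.7-fold and Gdf15 8.02-fold. Mdm2 rose 2.54-fold, a call that was lost without the first (adjusted p = 0.121) or second sham library (0.131) or the second irradiated library (0.0899). Ccng1, at 864 ± 12.8 CPM in sham libraries, had a log2 fold change of 0.43 ± 0.20 that did not pass. The connexin gene Gja1 (0.10 ± 0.14) and the natriuretic peptide gene Nppa (-0.14 ± 0.65, and 0.14 without the first irradiated library) did not pass either. Endothelial markers had stood at a median of 16.2% of their endothelial level and fibroblast markers at 7.88% of their fibroblast level in sham myocyte libraries.

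Several other lists moved in myocyte libraries at 6 hours with the preset correlation alone, none of them with a member past the threshold over all genes. Cell cycle genes had a median of -0.60 (5 lower adjusted over the list alone; adjusted p = 0.359 with an estimated correlation), MHC class II genes -0.79 (adjusted p = 0.308 with an estimated correlation), endothelial markers -0.32 (0.524), circadian genes -0.27 (0.516), interferon-stimulated genes -0.29 (0.734) and Notch pathway genes -0.29 (0.461). Heat shock genes had a median of -0.40 (adjusted p = 0.516 with an estimated correlation; 0.0735 without the first irradiated library), immediate-early genes -0.22 (0.414; 0.0588 without the same library), pericyte markers -0.27 (0.461; 0.0501 without the second sham library) and angiogenesis genes -0.26 (0.811; 0.32 without the second sham and 0.188 without the first irradiated library). With edgeR 46 of 14115 genes were called, all higher (571 had an unadjusted p below 0.05; DESeq2 called 7 lower and limma 0 lower). A fit of the 4 libraries alone called 224 higher and 328 lower, and the fit of all 36 called 128 higher and 43 lower. The count was 11 without the first sham library, 14 without the second, 21 without the first irradiated library and 16 without the second, and it was 148 (117 higher, 31 lower) with the first irradiated library of 7 days left out of the fit.

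At 7 days, Cdkn1a rose in myocyte libraries from 67.1 ± 8.17 to 323 ± 25.3 CPM (log2 fold change 2.27 ± 0.17, adjusted p = 0.000419). Of 32 p53 targets, 4 were higher (15 adjusted over the list alone), with a median of 0.56 and adjusted p = 0.00578 with an estimated correlation. Gdf15 rose 7.73-fold, Phlda3 4.63-fold and the carboxylesterase gene Ces2e 11.6-fold; without the second sham library these had adjusted p = 0.0872, 0.233 and 0.0872. The lower genes were Camk1d, a calmodulin kinase gene (-1.64), Sbk2, a kinase gene (-1.58), and Fras1, a matrix protein gene named here after its values were seen (-3.44). Without the second sham library they had adjusted p = 0.252, 0.252 and 0.233, and without the first Camk1d had 0.132 and Fras1 0.0763. The first irradiated library stood apart from the second: its log2 ratio to the second fell by 0.469 per doubling of transcript length, against -0.121 to 0.063 in the other 17 replicate pairs. Nppa stood at 2500 ± 748 CPM in sham and 803 ± 888 CPM in irradiated libraries and did not pass (log2 fold change -1.64 ± 0.67, adjusted p = 0.349); it was -3.85 without the first irradiated library (adjusted p = 0.000211) and -0.80 without the second (0.0404).

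Other lists were called at 7 days in myocyte libraries with the preset correlation, and most lost their call without some library. Oxidative phosphorylation genes had a median of 0.50 with no member called (adjusted p = 0.741 with an estimated correlation and 0.326 without the first irradiated library). Cardiac ion channel and calcium handling genes had a median of -0.32 (adjusted p = 0.643 with an estimated correlation). MHC class II genes had -0.71 (0.723; 0.572 without the first sham and 0.861 without the second irradiated library), cell cycle genes -0.23 (0.811; 0.365 and 0.794 without the same libraries), mesothelial markers 0.88 (0.568; 0.125 without the second sham and 0.305 without the second irradiated library) and basement membrane genes -0.32 (0.826; 0.796 without the first sham library, and turned in direction at 0.865 without the first irradiated library). The edgeR test called 12 of 14115 genes, 9 higher and 3 lower. Leaving out the second irradiated library keeps only the first, whose log2 ratio fell with transcript length. The count was 1 without the second sham library, 40 without the first irradiated library (22 higher, 18 lower) and 6718 without the second, and DESeq2 split its calls into 33 higher and 38 lower.

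At 28 days, Gdf15 rose 6.22-fold in myocyte libraries, Apln 4.16-fold and the p53-induced death gene Pmaip1 3.22-fold. Each of these calls was lost when libraries were left out: Gdf15 had adjusted p = 0.0672, 0.0735 and 0.132 without the first sham, second sham or first irradiated library. For Apln these were 0.209, 0.158 and 0.206, and Pmaip1 had 0.288, 0.447, 0.645 and 0.209 without each of the 4 libraries. The other called genes, named after their values were seen, were Zfp365 (2.45 ± 0.33; 0.292, 0.381, 0.206 and 0.294 without each library) and, lower, Cyp1a1 (adjusted p = 0.00955; 0.0662, 0.0735, 0.206 and 0.209), with too few reads after radiation for a fold. The 4 genes called higher and the 1 called lower were called the same way in endothelial libraries at 28 days. A response of myocytes and reads from endothelial cells in the preparation cannot be told apart for them. Of 32 p53 targets, 2 were higher (10 adjusted over the list alone), with a median of 0.44 and adjusted p = 0.00192 with an estimated correlation. Cdkn1a stood at 187 ± 20 CPM in sham and 331 ± 16.9 CPM in irradiated libraries (log2 fold change 0.82 ± 0.16), which did not pass (adjusted p = 0.203). Interferon-stimulated genes had a median of 0.38 with 0 of 41 called (12 higher adjusted over the list alone; adjusted p = 0.359 with an estimated correlation), and Isg15 had 1.30 ± 0.37 (adjusted p = 0.588).

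The remaining list calls in myocyte libraries at 28 days held with the preset correlation alone. Cell cycle genes had a median of 0.39 (adjusted p = 0.359 with an estimated correlation), MHC class II genes 0.60 (0.461), Notch pathway genes -0.33 (0.461), endothelial markers -0.38 (6 lower adjusted over the list alone; 0.3), macrophage and monocyte markers 0.39 (1 higher adjusted over the list alone; 0.598) and erythroid markers -0.74 (0.461). Inflammatory genes had a median of 0.12 (0.811; 0.53 without the first irradiated library, and turned in direction at 0.354 without the second sham library) and pericyte markers -0.25 (0.516; 0.486 without the second sham and 0.454 without the second irradiated library). The edgeR test called 5 of 14115 genes, 4 higher and 1 lower. The count was 1 without the first sham library, 0 without the second, 0 without the first irradiated library and 2 without the second, 98 (38 higher, 60 lower) with the first irradiated library of 7 days left out of the fit, and DESeq2 split its calls into 24 higher and 15 lower and the fit of the 4 libraries alone into 44 higher and 68 lower. For these counts of 0, 526 genes had an unadjusted p below 0.05 in the fit with all libraries, where DESeq2 called 39 genes and limma 4.

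No gene passed the edgeR F-test for a radiation effect that differed between times in myocyte libraries, where 510 of 14115 genes had an unadjusted p below 0.05, DESeq2 called 26 and limma 0. Cdkn1a (adjusted p = 0.419), Mdm2 (0.706) and Mki67 (0.419) did not pass. Without the first irradiated library of 7 days the count was 31 and Cdkn1a had adjusted p = 0.0107, Mdm2 0.0314 and Mki67 0.0379; without the second the count was 4509 and the values were 0.000176, 0.000147 and 0.000469. Each of these fits kept 1 irradiated library of 7 days, and without the second that is the library whose log2 ratio fell with transcript length. Its skew and a difference between times cannot be told apart in that fit. The p53 list differed between 28 days and 6 hours (median difference -0.55, adjusted p = 0.00826 with an estimated correlation). In simulated counts with this design, this F-test recovered 2% of genes changed 2-fold at 7 days in myocyte libraries (70% of those changed 4-fold), 79.6% in endothelial and 72% in fibroblast libraries. The simulated spread of the myocyte libraries took in the first irradiated library of 7 days.

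**Figure D4:**
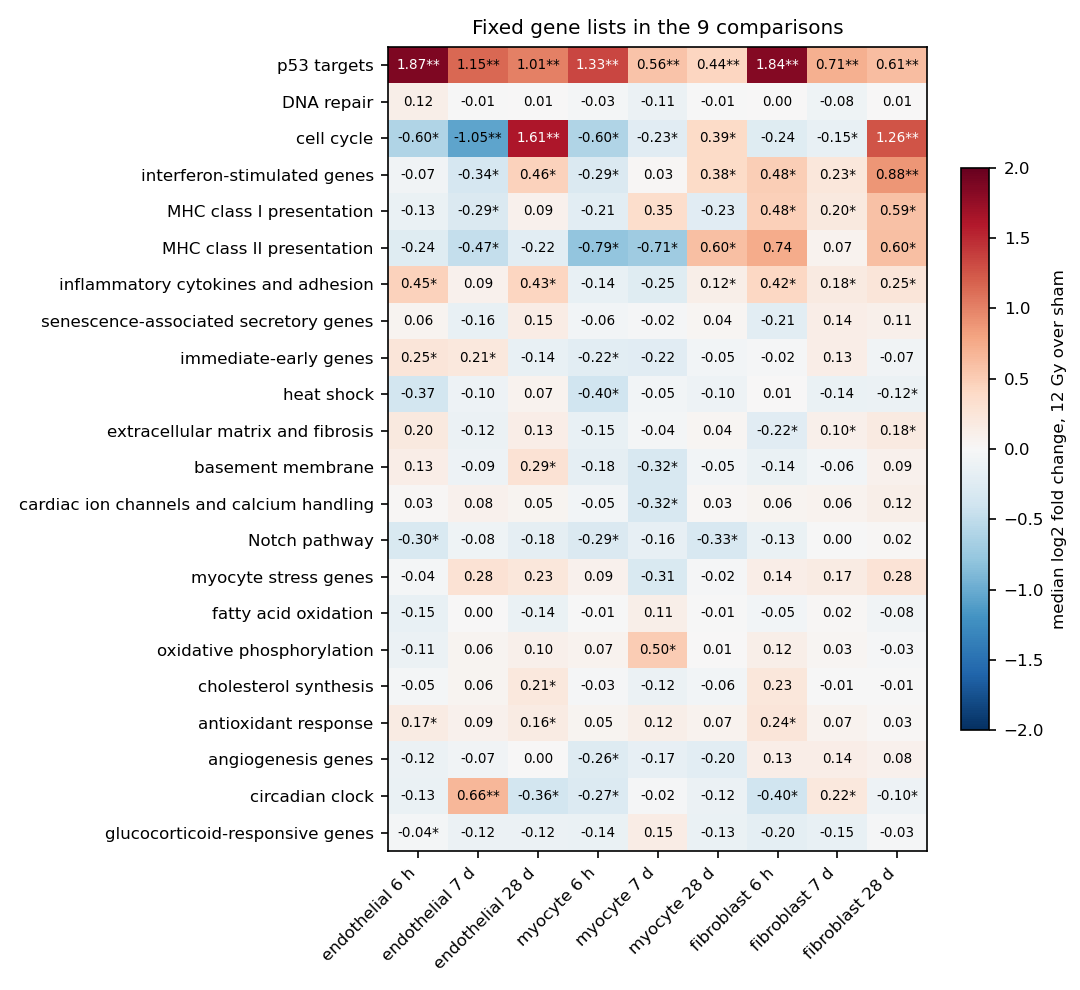
Median log2 fold change of 12 Gy over sham (numbers and colour scale) for the 22 program lists (vertical axis) in the 9 comparisons (horizontal axis), with * where camera with the preset correlation passed an adjusted p of 0.05 and ** where it also passed with an estimated correlation. p53 targets pass both ways in all 9 comparisons, and cell cycle genes go from -1.05 at 7 days to 1.61 at 28 days in endothelial libraries.

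The radiation effect differed between cell types for 343 of 16234 genes at 6 hours, 59 at 7 days and 60 at 28 days (edgeR F-test over all 36 libraries). At 6 hours Bcl3, a partner of NF-kB, had log2 fold changes of 0.39 in endothelial, 0.34 in myocyte and 3.29 in fibroblast libraries (adjusted p = 3.63e-08). Ccng1 had 2.71, 0.43 and 2.61 at 6 hours (adjusted p = 3.4e-08). Zfp365 (chromosome 10, 67886105 to 67912662) had 5.18, 3.55 and 2.35 at 6 hours (adjusted p = 4.75e-08), 3.71, 2.11 and 1.01 at 7 days (8.45e-07) and 3.4, 2.46 and 0.89 at 28 days (4.29e-06). At 28 days Pgf had 1.02, 0.66 and -0.72 (adjusted p = 6.44e-05). The p53 list rose less in myocyte than in endothelial libraries at 6 hours (median difference -0.40, adjusted p = 0.000394 with an estimated correlation), 7 days (-0.42, 0.00826) and 28 days (-0.32, 0.00867). It rose less in fibroblast than in endothelial libraries at 7 days (-0.48, 0.000394) and 28 days (-0.19, 0.0165). Cell cycle genes differed between fibroblast and endothelial libraries at 7 days (0.95, adjusted p = 0.0046 with an estimated correlation).

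Single libraries moved these counts. Without the second irradiated myocyte library of 7 days, its group keeps only the library whose log2 ratio fell with transcript length. At 6 hours the count was 227 without the first endothelial sham library, 191 and 213 without the first and second fibroblast sham library, 194 without the second irradiated fibroblast library and 1068 without the first irradiated myocyte library of 7 days. At 7 days it was 20 and 19 without the first and second endothelial sham library, 27 and 21 without the irradiated endothelial ones, 39 without the first fibroblast sham library, 32 and 34 without the irradiated fibroblast ones and 5855 without the second irradiated myocyte library. At 28 days it was 30 without the second endothelial sham library, 224 and 39 without the irradiated endothelial ones, 107 without the first myocyte sham library, 31 and 27 without the fibroblast sham libraries, 30 and 25 without the irradiated fibroblast ones, and 198 without the first irradiated myocyte library of 7 days.

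Calls overlapped between cell types and times. Of 13390 genes tested in all cell types, 45 were higher at all 3 times in both endothelial and fibroblast libraries, and 2, Gdf15 and Zfp365, were higher in all 9 comparisons (in myocyte libraries at 28 days, without the first irradiated library, they had adjusted p = 0.132 and 0.206). Of the 46 genes higher in myocyte libraries at 6 hours, 45 were also higher in endothelial libraries at 6 hours, where 2.89 would fall by chance. That chance value takes the calls as independent, while sham myocyte libraries held endothelial markers at a median of 16.2% of their endothelial level. All 9 genes higher in myocyte libraries at 7 days were also higher in endothelial libraries at 7 days, while none of the 3 lower was lower there. At 28 days the 4 genes higher and the 1 lower in myocyte libraries were called the same way in endothelial libraries. A response of myocytes and reads from endothelial cells in the preparation cannot be told apart in these overlaps. At 28 days endothelial and fibroblast libraries shared 194 genes higher after radiation, against 21.6 by chance. This chance value takes the calls as independent as well. Sham endothelial libraries held fibroblast markers at a mean log2(CPM + 1) of 7.04, against 10.91 in fibroblast libraries. How far reads from fibroblasts in endothelial libraries add to this overlap was not tested. Of 133 genes lower in endothelial libraries at 7 days, 78 were higher there at 28 days.

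Some fixed lists passed in none of the 9 comparisons. DNA repair genes had their smallest adjusted p, 0.17, in fibroblast libraries at 7 days, although 4 of 25 were higher in endothelial libraries at 6 hours, including Brca2 (2.24-fold). The smallest adjusted p was 0.147 for senescence-associated secretory genes, 0.0623 for myocyte stress genes and 0.0556 for fatty acid oxidation genes. Among marker lists it was 0.0622 for B cells, 0.0695 for neutrophils, 0.101 for T and NK cells, 0.351 for Schwann cells and 0.628 for adipocytes.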

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

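The tests of explanations in this part were chosen after the results were seen; the tests between times and between cell types were planned. Results are given here because a library lay far from the others of its group, or because the radiation effect differed between times or cell types.

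The first pattern is the rise of cell cycle genes at 28 days in endothelial and fibroblast libraries. The summed level of the 42 genes rose by 411 CPM (SE 45.1) in endothelial and by 163 CPM (SE 6.46) in fibroblast libraries. The immune marker lists changed by -2.98 CPM (SE 3.6) and 0.00993 CPM (SE 3.42), which argues against a larger amount of immune cells in the irradiated preparations. These sums cannot show whether the immune cells present divided more. Mesothelial cells and pericytes were not tested in this way. Fibroblasts among the endothelial cells fall short, since the endothelial rise exceeded the fibroblast rise by 248 CPM, and the endothelial share of 0.475% in fibroblast libraries would bring 1.95 CPM, leaving 161 CPM. Low sham values at 28 days are argued against by 34 of 42 genes in endothelial and 32 of 42 in fibroblast libraries with both irradiated libraries above all 6 sham libraries of the cell type. A candidate explanation that stays open, and was not tested, is that more endothelial cells and fibroblasts were dividing 28 days after radiation, and a change in which subsets of each cell type were recovered is another.

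The second pattern is the rise of p53 targets in myocyte libraries at 6 hours. Endothelial markers stood at a median of 16.2% and fibroblast markers at 7.88% of their level in their own libraries, and both cell types raised p53 targets. The observed rise over the rise that these shares would bring had a lower quartile of 1.19 and a median of 1.45 over the 29 of 32 targets to which the shares would bring a rise of more than 1 CPM, and 27 of these 29 lay above 1. The median was 0.987 at 7 days (26 such targets) and 1.38 at 28 days (23). A response of the myocytes themselves and reads from the other cells in the preparation cannot be told apart with that lower quartile: the shares rest on marker genes alone (quartiles over the endothelial markers 15.0% and 19.9%), and the calculation assumes that these cells responded as those in their own libraries did.

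The third pattern is the first irradiated myocyte library of 7 days. Its log2 ratio to the second library fell by 0.469 per doubling of transcript length, with the other 17 replicate pairs at -0.121 to 0.063, and length took 42.7% of the variance, so a skew with transcript length is a candidate explanation. The log2 ratios of cardiomyocyte markers, which a change in their share would move together, had an SD of 0.814. The other 5 myocyte pairs had 0.125 to 0.359. The skew itself spreads markers of unlike transcript length, so this SD cannot decide whether the mix of cell types also differed. What produced the skew is not known, and no biological explanation was tested.

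Of 39 groups of 6 sham libraries, 3 held a library far from the rest, where chance gives about 1 in 20 groups. The gap over the range was 0.818 for adipocyte markers in the second endothelial sham library of 6 hours, 0.648 for macrophage and monocyte markers in the second myocyte sham library of 7 days and 0.67 for neutrophil markers in the first myocyte sham library of 28 days. The adipocyte markers stood at a mean log2(CPM + 1) of only 0.25 in that library, against 0.06 in the nearest, so this gap lies near the floor.

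Here single libraries were left out only of the comparisons that they are part of. Fits without the first irradiated myocyte library of 7 days, for the other times, are given apart and are not in the spans below. The radiation effect differed between times for 934 genes in endothelial and 1484 in fibroblast libraries, and between cell types for 343 genes at 6 hours, 59 at 7 days and 60 at 28 days (edgeR F-tests). Without single libraries these counts spanned 441 to 1504, 901 to 1634, 191 to 382, 19 to 5855 and 25 to 224. The lowest values came without the second endothelial sham library of 28 days (441), the second irradiated fibroblast library of 6 hours (901), the first fibroblast sham library of 6 hours (191), the second endothelial sham library of 7 days (19) and the second irradiated fibroblast library of 28 days (25). The highest came without the first irradiated endothelial library of 28 days (1504 and 224), the first irradiated fibroblast library of 28 days (1634) or 6 hours (382) and the second irradiated myocyte library of 7 days (5855); the report gives the others that moved a count by more than 1.5 times. In endothelial libraries the effect differed between times for Mki67 (adjusted p = 7.49e-06), Top2a (7.49e-06), Ccng1 (3.22e-05), Mdm2 (0.000175) and Isg15 (0.000279). In fibroblast libraries it did so for Ccng1 (2.71e-07), Cdkn1a (6.22e-07), Mdm2 (3.92e-06), Mki67 (3.53e-05), Top2a (8.35e-05), Gja1 (0.000333), Postn (0.00398), Ccl2 (0.00442) and Col1a1 (0.00655).

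Between cell types at 6 hours the effect differed for Ccng1 (adjusted p = 3.4e-08), Gja1 (0.00211), Mdm2 (0.00821), Cdkn1a (0.00946) and Isg15 (0.0107). That of Cdkn1a had adjusted p = 0.08 without the second fibroblast sham library, that of Mdm2 0.0505 and 0.0759 without the first myocyte sham or irradiated library, and that of Isg15 0.102 and 0.115 without the second fibroblast sham or irradiated library. At 7 days it differed for Ccng1 (1.35e-05), Mki67 (0.00439; 0.055 without the second irradiated endothelial library) and Mdm2 (0.0257). Mdm2 had 0.0598 and 0.16 without the first and second endothelial sham library, 0.161 without the second irradiated endothelial library and 0.0627 without the second myocyte sham library. At 28 days it differed for Ccng1 (0.0257). That call was lost without the first or second endothelial sham (0.149, 0.101), second irradiated endothelial (0.0998), first or second myocyte sham (0.0846, 0.0824), first irradiated myocyte (0.174), first or second fibroblast sham (0.0707, 0.0737) or first or second irradiated fibroblast library (0.0641, 0.0692).

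The effect on gene lists differed between times in 9 cases with an estimated correlation. Circadian genes in endothelial libraries differed between 7 days and 6 hours (median difference 0.86, adjusted p = 0.0399) and between 28 and 7 days (-1.12, 0.0294), and cell cycle genes there between 28 and 7 days (2.51, 0.00192) and between 28 days and 6 hours (2.20, 0.00826). p53 targets differed between 28 days and 6 hours in myocyte libraries (-0.55, 0.00826), and between 7 days and 6 hours (-1.06, 0.000394) and 28 days and 6 hours (-1.13, 0.000394) in fibroblast libraries. Cell cycle genes (1.51, 0.00817) and interferon-stimulated genes (0.62, 0.0394) differed between 28 and 7 days in fibroblast libraries.

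Between cell types, lists differed in 10 cases. At 6 hours the log2 fold changes of p53 targets were lower in myocyte than in endothelial (median difference -0.40, adjusted p = 0.000394) and fibroblast libraries (-0.24, 0.00627), and antioxidant genes lower in myocyte than in fibroblast libraries (-0.30, 0.0212). At 7 days p53 targets (-0.42, 0.00826) and circadian genes (-0.71, 0.0251) were lower in myocyte than in endothelial libraries, p53 targets lower (-0.48, 0.000394) and cell cycle genes higher (0.95, 0.0046) in fibroblast than in endothelial libraries. At 28 days p53 targets (-0.32, 0.00867) and cell cycle genes (-0.77, 0.0464) were lower in myocyte, and p53 targets lower in fibroblast (-0.19, 0.0165) than in endothelial libraries.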

How the results depend on the processing

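Chosen after the data were seen were the sum over transcripts, the replicate block within each time and the fit without the first irradiated myocyte library of 7 days; all other settings were planned. Of 271 results for named genes, 179 kept their direction and their side of the threshold in every setting. Over all 4416 values, 4141 were so kept, 227 lost the call and 45 gained it. Another 3 turned in direction without a call in either setting, and 0 turned in direction with a call in at least 1. A further 20 could not be computed because the gene was not tested. RLE size factors kept 271 of 271, DESeq2 262, limma 251, no low-count filter 259 and the sum over transcripts 267. All 36 libraries in one fit kept 181 of 216 (32 lost the call) and the fit of the 4 libraries 190 of 216 (21 lost). The filter at a mean of 5 CPM kept 252 of 253, library sizes without hemoglobin and ribosomal RNA genes 269 of 269, and the fit without the first irradiated myocyte library of 7 days 38 of 41 (3 gained the call). With each library left out in turn, where the lone library of a group is assumed to vary like the other groups, 1379 of 1524 values were kept. RLE size factors, library sizes without hemoglobin and ribosomal RNA genes and the sum over transcripts kept all 15 counts of genes within 1.5 times.

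The counts of genes that moved by more than 1.5 times are given by setting, and the cause was not tested unless stated. DESeq2 called 80 genes in myocyte libraries at 6 hours, 71 at 7 days and 39 at 28 days. For differences between times it called 1454 in endothelial and 26 in myocyte libraries, and for differences between cell types 750 at 6 hours, 297 at 7 days and 256 at 28 days. limma on log2(RPKM + 1) called 176 genes in fibroblast libraries at 7 days and 5 in myocyte libraries at 7 days, and for differences between cell types 602, 131 and 228 at 6 hours, 7 days and 28 days.

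Without a low-count filter the counts were 674 and 2424 in endothelial libraries at 7 and 28 days, 844 and 930 in fibroblast libraries at 7 and 28 days, and 111, 600 and 90 in myocyte libraries at 6 hours, 7 days and 28 days. The differences between times gave 2161 in endothelial, 2456 in fibroblast and 129 in myocyte libraries, and those between cell types 787, 631 and 272. A filter at a mean of 5 CPM, which tests fewer genes, gave 30 and 2 in myocyte libraries at 6 hours and 28 days.

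All 36 libraries in one fit, which share 1 spread per gene, gave 991 (583 higher, 408 lower) in endothelial libraries at 28 days. It gave 1310 (850 and 460), 51 (50 and 1) and 188 (178 and 10) in fibroblast libraries at 6 hours, 7 days and 28 days, and 171 (128 and 43), 1437 (1019 and 418) and 93 (46 and 47) in myocyte libraries. A fit of the comparison's 4 libraries gave 792 and 793 in endothelial libraries at 6 hours and 28 days, and 552 (224 higher, 328 lower), 0 and 112 (44 higher, 68 lower) in myocyte libraries at 6 hours, 7 days and 28 days. For the 0, edgeR with all 12 libraries gave 12, 1974 genes at an unadjusted p below 0.05, DESeq2 71 and limma 5. Without the first irradiated myocyte library of 7 days the counts were 148 and 98 in myocyte libraries at 6 hours and 28 days, and 1068 and 198 for differences between cell types at 6 hours and 28 days. In that fit the spread is estimated without the library, so the comparisons that it is no part of changed through the shared fit.

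The replicate block gave 432 in fibroblast libraries at 7 days, 6 in myocyte libraries at 7 days and 2 at 28 days. A replicate block within each time gave 21, 4 and 1 in myocyte libraries at 6 hours, 7 days and 28 days, 29 and 34 for differences between cell types at 7 and 28 days, and 16 lists in endothelial libraries at 7 days. Of the 271 results for named genes the replicate block kept 264 and the block within each time 258. Within a time, no pairing of libraries by replicate number was seen. Correlations of deviations from the group mean lay between -0.11 and 0.11 over 9 pairs of sham and irradiated libraries with equal numbers. Across cell types they lay between -0.03 and 0.09 over 18 pairs. Pairing across times was not looked at in this way, and the replicate block raised the fibroblast count at 7 days from 276 to 432. Which libraries share animals is not given in the labels.

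With each library left out, counts of genes ranged from 826 to 1553, 155 to 212 and 443 to 2317 in endothelial libraries at 6 hours, 7 days and 28 days. In fibroblast libraries they ranged from 2198 to 3007, 101 to 435 and 229 to 416, and in myocyte libraries from 11 to 21, 1 to 6718 and 0 to 2. For differences between times they ranged from 441 to 1504 in endothelial, 901 to 1634 in fibroblast and 0 to 4509 in myocyte libraries, and for differences between cell types from 191 to 382, 19 to 5855 and 25 to 224. In these ranges a library was left out only of the comparisons that it is part of. Counts for the other times without the first irradiated myocyte library of 7 days are given above and are not among them. The report names each library that moved a count by more than 1.5 times.

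Of 309 results for gene lists, 76 were kept in every setting, and of 2839 values 2307 were kept, 185 lost the call and 153 gained it. Another 188 turned in direction without a call in either setting, and 6 turned in direction with a call in at least 1. With an estimated correlation, 1, 3 and 2 lists passed in endothelial libraries at 6 hours, 7 days and 28 days, 1, 1 and 1 in myocyte libraries, and 1, 1 and 3 in fibroblast libraries. With fry, 3 and 5 passed in endothelial libraries at 7 and 28 days, 1, 1 and 1 in myocyte libraries, and 1 and 4 in fibroblast libraries at 7 and 28 days. With each library left out, the number of lists ranged from 9 to 14 and 11 to 16 in endothelial libraries at 6 hours and 7 days, 7 to 12 in fibroblast libraries at 28 days and 5 to 13 in myocyte libraries at 7 days.

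Of the 188 list values that turned in direction without a call in either setting, 162 came with each library left out in turn. The rest came with fry (7), the 4 libraries alone (8), the replicate block (2) and the block within each time (6), and 3 without the first irradiated myocyte library of 7 days. The 6 lists that turned in direction with a call in at least 1 setting did so when a library was left out. Their adjusted p ranged from 3.64e-05 to 0.865 for basement membrane genes and from 3.64e-05 to 0.831 for extracellular matrix genes in myocyte libraries at 7 days, and from 5.89e-14 to 0.708 for endothelial markers in fibroblast libraries at 6 hours. It ranged from 0.0326 to 0.131 for fibroblast markers in myocyte libraries at 28 days, from 0.0157 to 0.943 for glucocorticoid-responsive genes in fibroblast libraries at 7 days, and from 2.78e-07 to 0.53 for inflammatory genes in myocyte libraries at 28 days.

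Of 39 marker differences between cell types, 33 were kept with the median for the mean and with RPKM for CPM. Of 78 values 69 were kept, and 1 lost and 4 gained the call. Another 2 turned in direction without a call in either setting, and 2 turned in direction with a call in at least 1. With RPKM, the difference of T and NK cell markers between myocyte and fibroblast libraries became -0.06, and that of Schwann cell markers between endothelial and myocyte libraries became 0.02. The myocyte libraries were the shallowest and had the widest fitted spread, which took in the first irradiated library of 7 days. The SD of log2 ratios between replicates was 0.699 in that library's pair and 0.125 to 0.296 in the other 17 pairs. In counts simulated with this spread, the test of irradiated against sham recovered 32% of genes changed 2-fold at 7 days in myocyte libraries. It recovered 85.7% in endothelial and 74% in fibroblast libraries.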

Other observations

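The fit without the first irradiated library of 7 days was chosen after the data were seen, and the values are given without an explanation. In myocyte libraries at 28 days Cdkn1a did not pass with edgeR (log2 fold change 0.82, adjusted p = 0.203); it had 0.00263 with DESeq2 and 0.0069 without the first irradiated library of 7 days, but 0.238 with limma and 0.25 with the filter at a mean of 5 CPM. Endothelial marker levels in myocyte libraries at 28 days were 7.95 and 8.20 in sham and 7.62 and 7.62 in irradiated libraries, as mean log2(CPM + 1). Hemoglobin genes took 0.199% and 0.180% of reads in the sham and 0.1% and 0.134% in the irradiated myocyte libraries of 28 days.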
